A study of Homo sapiens with 9 samples.

How the data were processed

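Per the labels, KYSE30 cells were transfected with Lipofectamine and harvested on day 3, RNA was extracted with Trizol, and biotin-labeled cRNA was made with an Ambion MessageAmp kit for Illumina arrays. Each of the 9 groups has 1 array, and each array was assigned to its group from its label. The array version, the scanner software, the arm of miR-455 and the make-up and doses of the combinations are not given in the sources used here.

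The deposited raw table holds, per the file headers, a signal intensity on a linear scale for each of 47317 probes and array, with no background correction or normalization recorded. The same deposited table gives a detection p-value for each probe and array, per the file headers. A further deposited table of processed intensity values, made by the authors, follows the raw signal of each array as a straight line, with a background level subtracted and the arrays scaled to an equal mean, and its values are on a linear scale. How the authors computed it is not given in the sources used here.

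Raw intensities were background corrected, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 (R 4.3.3), which takes the background from the detection p-values and adds an offset of 16. All 9 arrays were normalized together. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A probe was compared between 2 arrays where its detection p was under 0.01 on at least 1 of them. On an array where it was not detected, its value was the higher of its own and the lowest value among detected probes of that array, so that such differences are lower bounds. A probe counted as different at a log2 difference of at least 1. Correlations, covariances and principal components used the 12202 probes detected on all 9 arrays, and 28311 probes were detected on none. With 1 array per group, a rule of size replaced a test and no p-value was computed across probes. Exact permutation p-values of a correlation of array brightness with the first 2 components over 7 arrays were computed and are not given, because the arrays fall into separate clusters.

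The files give probe numbers without gene names, and none of these numbers occurs in the reference gene table used here. The 27 gene lists, the cell type markers, the 9 lists of microRNA seed sites, the levels of PIK3R1 and PIK3R3 and the rule of the brightest probe per gene, all fixed before the data were examined, were therefore not analysed here. The rule for named genes was reduced to the 2 highest and 2 lowest probes, ranked by the smallest difference in size among siPIK3R1, siPIK3R3 and the siRNA combination, where all went the same way and were detected along with the control. Analyses of the number of shared probes, of probes set apart in 2 arrays, of the difference between the combinations and of single arrays other than the control as references, outside the planned microRNA pairings, were chosen after the data were seen.

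Because the 8 comparisons share 1 control array, unchanged arrays were simulated from the mean levels, the background of each array and a noise taken from miR-32 and miR-455, the closest pair, and 200 probes were changed by known folds in siPIK3R1 and left out of all values for unchanged arrays. The noise is that of different transfections and so may overstate that of repeats. It was also taken from the closest pair and given to every array, so it may understate the noise of the others. The first simulation used noise by level, which counts background noise a second time, and gave 21 to 96 unchanged probes at 2-fold and covariances of 0.030 to 0.033. It was replaced, after its results were seen, by one with the noise of the brightest of 10 bins of probes, which gave 9 to 75 unchanged probes and covariances of 0.024 to 0.026. The standard deviation of the miR-32 minus miR-455 difference is 0.200 as measured, 0.204 in the second simulation and 0.235 in the first. The noise was taken from this same pair, so the likeness is no separate check. The second gave 10 probes at 2-fold and 697 at 1.5-fold between these 2 arrays, where 7 and 218 were measured, so it overstates the noise of dim probes. Simulated lists held only 9 to 75 probes, so simulated overlaps are small by list length. They show how few shared calls noise alone gives, not how far longer lists would overlap. Overlaps are also set against independent lists, the product of the 2 list sizes over the probes compared in both.

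Alternatives fixed before the data were examined were no background correction, an offset of 50, median scaling, the processed values on the log2 scale with a floor of 16, the median of the 8 other arrays as the reference, a detection p under 0.05, no detection filter and a threshold of 1.5-fold. Single-agent arrays as the reference for the combinations, normalization without the combination arrays and the removal of probes high in nearly all transfections were added after seeing the data.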

Results

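KYSE30, an established line of human esophageal squamous cell carcinoma, was transfected with a microRNA, a small interfering RNA (siRNA) or a mixture, and gene expression was measured on Illumina arrays in RNA taken on day 3. Per the series title, the question was how expression changes when miR-32, miR-455, miR-181a or miR-181b is raised, or when PI3K is knocked down. PIK3R1 and PIK3R3, the targets of the siRNAs, encode regulatory subunits of PI3K, a lipid kinase of growth factor signaling. The 9 groups had 1 array each: the 4 single microRNAs, a microRNA combination, the 2 single siRNAs, an siRNA combination and a negative control. No value below has a replicate error, no p-value is given, and a difference between arrays may be a difference between cultures. Each array measured 47317 probes, which the files name only by probe number, so the results are given for probes and sets of probes. The knockdown of PIK3R1 and PIK3R3, which would check the siRNA labels, was not analysed here for the same reason.

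Detection was similar across the arrays, while signal was lower on both combination arrays. At a detection p under 0.01, between 14304 probes (miR-181b) and 15775 probes (miR-32) were detected per array, and 12202 probes were detected on all 9. The mean raw signal was 452 for miR-32, 468 for miR-455, 418 for miR-181a, 361 for miR-181b, 343 for siPIK3R1, 392 for siPIK3R3 and 406 for the control. It was 270 for the microRNA combination and 223 for the siRNA combination, whose background levels of 60.4 and 53.2 were also below those of the other 7 arrays (77.3 to 88.7). The number of arrays limits the precision of every comparison.

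**Figure D1:**
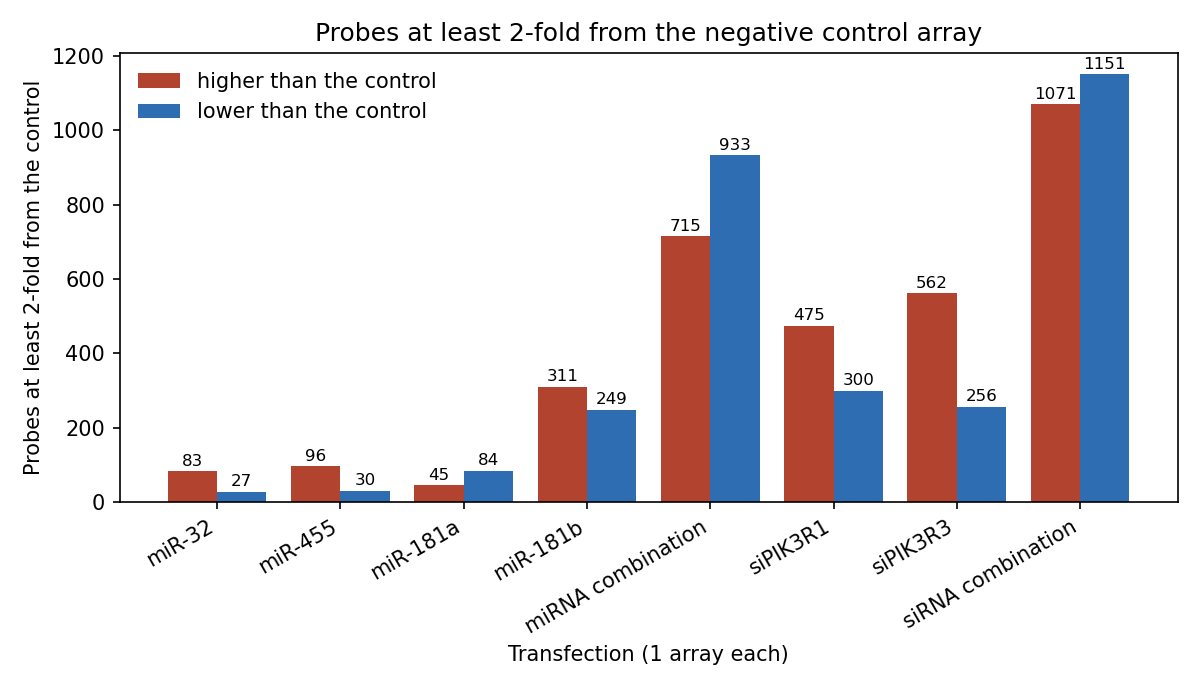
Number of probes at least 2-fold higher (red) or lower (blue) than in the negative control array, for each of the 8 transfections (1 array each, no error bars). The counts run from 110 probes in all for miR-32 to 2222 for the siRNA combination.

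The miR-32 and miR-455 transfections differed from the control at few probes, as did miR-181a, which had the fewest of the 3 without background correction or with an offset of 50. In miR-32, 83 probes were at least 2-fold higher and 27 lower, of 16449 compared, and in miR-455 96 were higher and 30 lower, of 16096. The highest probe detected on both arrays stood 3.58 above the control on the log2 scale in miR-32 and 3.43 in miR-455. The 2 arrays were also the closest pair of all 36, with 7 probes at least 2-fold apart and a correlation of 0.994 across probes. Of the 83 probes higher in miR-32, 68 were also higher in miR-455, against 0.51 for independent lists and 2 for simulated unchanged arrays that share the control. Of the same 83 probes, 80 were also higher in siPIK3R3 and 77 in miR-181b, so this overlap was not particular to miR-455. For miR-32 and miR-455 against the control, simulated unchanged arrays gave 24 and 21 probes at 2-fold. At 1.5-fold they gave 819 and 734, near the 691 and 851 measured. However, the simulation overstates 1.5-fold calls, with 697 simulated against 218 measured between miR-32 and miR-455. It therefore cannot show whether the 1.5-fold differences exceed noise. The share of higher probes in miR-32 was 75.5%, and 62.9% in the authors' processed values or 64.3% with median scaling. Against the median of the other 8 arrays most probes were lower instead, with 7 higher and 67 lower in miR-32 and 3 higher and 39 lower in miR-455. The counts were 59 and 68 without background correction and 205 and 221 in the authors' processed values.

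The miR-181a and miR-181b transfections, whose microRNAs share a seed sequence, gave different results. In miR-181a, 45 probes were at least 2-fold higher than in the control and 84 lower, of 15871 compared, with a highest fold of 4.45 among probes detected on both arrays. In miR-181b, 311 were higher and 249 lower, of 15917, and the highest fold was 24.7. The balance in miR-181b turned without a detection filter (404 higher, 431 lower) and at 1.5-fold (1268 higher, 1440 lower). Set against each other, 316 probes were at least 2-fold higher in miR-181a and 497 higher in miR-181b, a total of 813. Of 43 probes higher in miR-181a among those compared in both, 21 were also higher in miR-181b, against 0.77 for independent lists and 1 simulated. Of 84 lower probes, 32 were also lower in miR-181b, against 1.36 and 0. The miR-181a array also shared 26 higher and 22 lower probes with siPIK3R3, so such overlap was not particular to miR-181b. The correlation of the differences from the control was 0.16 across probes, which are not independent replicates, below the 0.45 of simulated unchanged arrays, and its covariance of 0.025 lay within the 0.024 to 0.026 of simulated unchanged arrays. With differences that share no array, the correlation was -0.24 (miR-181a minus miR-32 with miR-181b minus miR-455) and -0.23 with the references exchanged, and -0.03 in the third pairing, of miR-181a minus miR-181b with miR-32 minus miR-455. The sign depended on the references, with correlations from -0.34 to 0.09 over 12 choices of 2 among miR-32, miR-455, siPIK3R3 and the control. The higher share for miR-181a was 34.9%, 46.3% in the authors' processed values and 18.9% against the median of the other 8 arrays. The count for miR-181a ranged from 43 without background correction to 244 against the median of the other 8 arrays, both at 2-fold, and the count for miR-181b was 242 and 176 in these settings.

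The siPIK3R1 and siPIK3R3 transfections each differed from the control at more probes than any single microRNA. In siPIK3R1, 475 probes were at least 2-fold higher and 300 lower, of 15985 compared. In siPIK3R3, 562 were higher and 256 lower, of 15918, and 110 were at least 4-fold higher against 36 in siPIK3R1. At 1.5-fold the directions were nearly even in siPIK3R3, with 1371 higher and 1358 lower. Among probes detected on both arrays, the highest folds were 26.9 for siPIK3R1 and 56.8 for siPIK3R3. The 2 siRNAs shared 149 higher probes, of 454 and 482 among the probes compared in both, against 14.3 for independent lists and 1 for simulated unchanged arrays. With miR-181b, siPIK3R1 shared 171 higher probes and siPIK3R3 shared 198, so such overlap was not particular to the siRNAs. The correlation of the differences of siPIK3R1 and siPIK3R3 was 0.24, below the 0.47 of simulated unchanged arrays that share the control. The covariance was 0.069, against 0.025 simulated. With 2 different microRNA arrays as references, so that no array was shared, the correlation ranged from -0.50 to 0.23 over 12 choices. The share of higher probes in siPIK3R1 was 61.3%, and 71.3% with median scaling, and without background correction the counts were 319 for siPIK3R1 and 458 for siPIK3R3. Simulated data recovered 98% of 4-fold higher, 84% of 4-fold lower, 42% of 2-fold higher and 46% of 2-fold lower probes in siPIK3R1. Probes set at the 2-fold threshold itself are called about as often as not by construction.

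**Figure D2:**
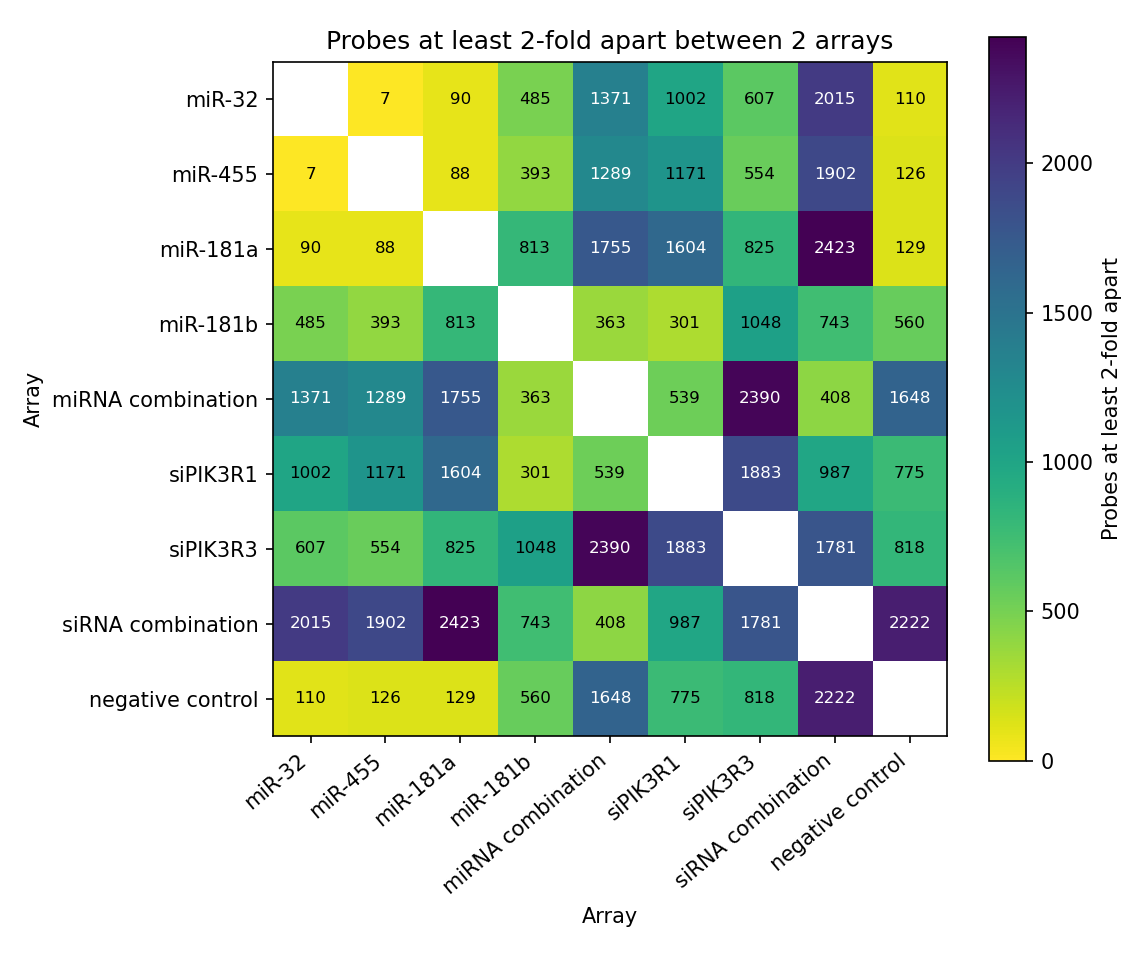
Number of probes at least 2-fold apart between each 2 of the 9 arrays (1 array per group, color scale from 0). The lowest count is 7, between miR-32 and miR-455, and the highest is 2423, between miR-181a and the siRNA combination.

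A small set of probes was higher in every transfection except miR-181a. Of all probes, 60 were at least 2-fold higher than in the control in each of the 7 other transfections, 4 of which were also 2-fold higher in miR-181a, while no simulated probe was. None was 2-fold lower in all 7. A stricter set of 51 probes was at least 2-fold lower in the control and in miR-181a than in each of the other 7 arrays. Its median fold over the control was 3.22 in miR-32, 3.04 in miR-455, 5.85 in miR-181b, 5.62 in the microRNA combination, 5.39 in siPIK3R1, 13.7 in siPIK3R3 and 11.9 in the siRNA combination, and the median log2 difference in miR-181a was -0.25. Of these 51, 44 were detected in the control, and the folds of the others are lower bounds. They were chosen for this arrangement, so their direction is no separate evidence of it.

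**Figure D3:**
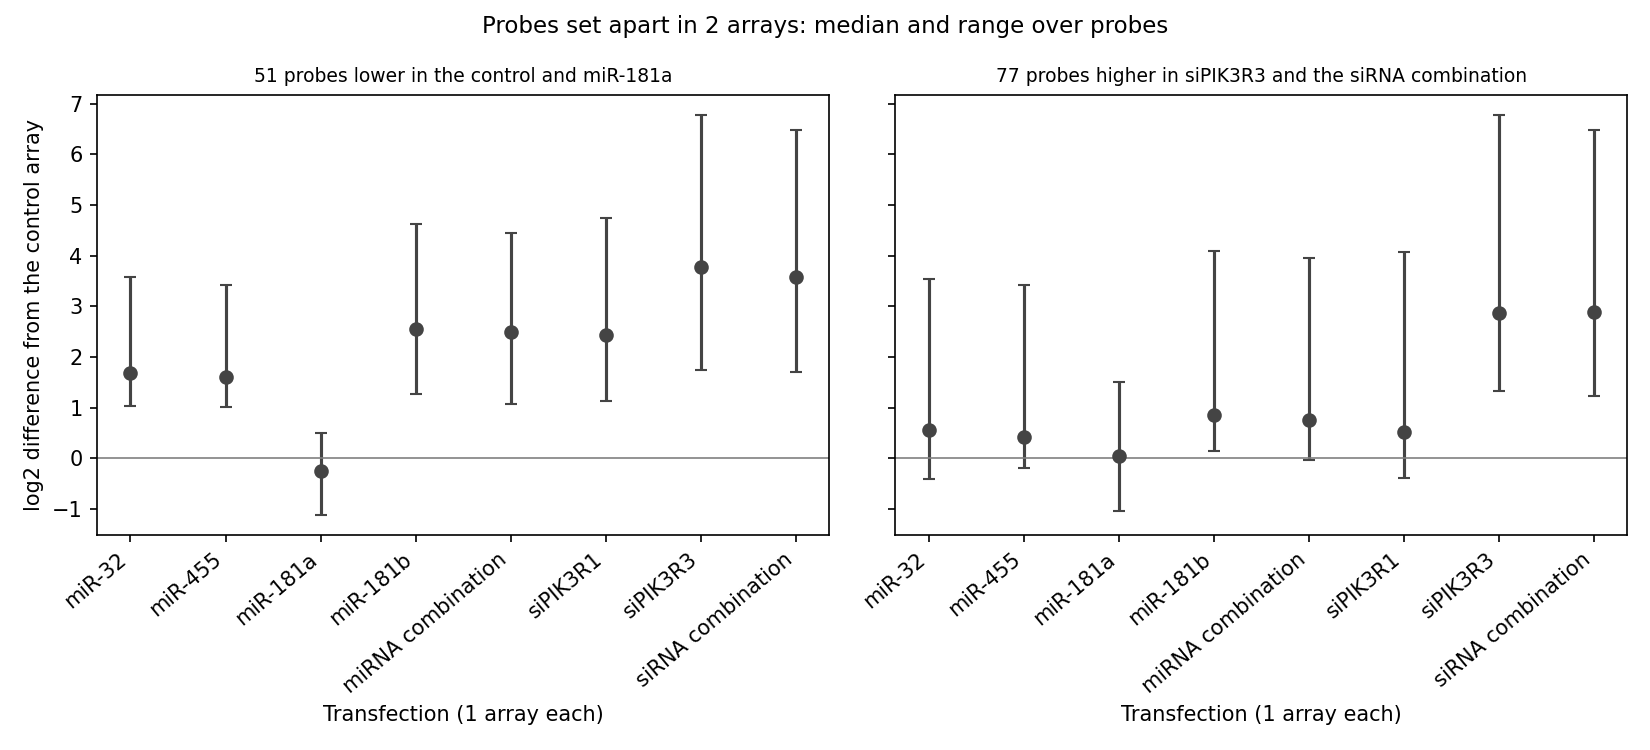
Median (points) and range over probes (bars) of the log2 difference from the negative control array, for the 51 probes lower in the control and miR-181a than in all other arrays (left) and the 77 probes higher in siPIK3R3 and the siRNA combination than in all other arrays (right), at 2-fold. On the left the median is highest in siPIK3R3, at 3.77. On the right it is 2.87 in siPIK3R3 and 2.88 in the siRNA combination. Only 37 of the 77 probes on the right were detected in the control, and the other differences are lower bounds. A probe could belong to both sets.

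The 4 probes named by the reduced rule, 2 highest and 2 lowest by the smallest difference among both siRNAs and their combination, were ILMN_1662358, ILMN_1674063, ILMN_1739441 and ILMN_1709067. ILMN_1662358 was 4.75 higher than the control on the log2 scale in siPIK3R1, 4.80 in siPIK3R3 and 5.16 in the siRNA combination. ILMN_1674063 was 4.42, 4.89 and 5.62 higher in the same order. Both were also over 3 higher in miR-32, miR-455, miR-181b and the microRNA combination, and lower in miR-181a, at -0.64 and -0.99. ILMN_1739441 differed by -1.96, -1.48 and -1.89, and its difference in miR-181a was -3.03. ILMN_1709067 differed by -1.50, -1.25 and -1.97. Both were lower than the control in every other transfection too. ILMN_1739441 differed by -0.84 in miR-32, -2.01 in miR-455, -1.02 in miR-181b and -1.86 in the microRNA combination. ILMN_1709067 differed by -0.31, -0.70, -1.76 and -1.59 in the same order, and by -0.37 in miR-181a. Against the median of the other 8 arrays, 9 of the 12 differences in both siRNAs and their combination were under 2-fold. There ILMN_1662358 was 0.74 higher in siPIK3R1 and ILMN_1739441 was 0.40 higher in siPIK3R3. The rule was applied to probes, and over all probes of these 3 comparisons 45.0% kept one sign, against 50.1% in simulated unchanged arrays.

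Of the single agents, miR-181b and siPIK3R1 resembled each other and both combinations. Across probes, the differences of miR-181b and siPIK3R1 from the control correlated at 0.72, against 0.45 simulated, with a covariance of 0.184 against 0.026 simulated. Their correlation lay between 0.37 and 0.71 over 12 choices of 2 references among miR-32, miR-455, miR-181a and siPIK3R3. All of these references lay on the other side of the first principal component described below, so they cannot remove that axis. The differences of miR-181b correlated at 0.76 with the microRNA combination and at 0.77 with the siRNA combination, and those of siPIK3R1 at 0.73 and 0.71, against 0.50, 0.48, 0.48 and 0.48 for simulated unchanged arrays that share the control. Over the same 12 choices of references, these 4 correlations ranged from 0.32 to 0.66, 0.19 to 0.71, 0.39 to 0.68 and 0.25 to 0.69. These 4 arrays also had the 4 lowest mean raw signals of the 9, from 223 to 361, against 392 to 468 on the other 5. The first principal component, with 52.6% of the variance, had miR-181b, siPIK3R1, the microRNA combination and the siRNA combination at -0.12, -0.22, -0.33 and -0.42 and the other 5 arrays between 0.14 and 0.30.

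Both combinations differed more from the control than any of their single agents. In the microRNA combination, 715 probes were at least 2-fold higher and 933 lower, of 16555 compared, and in the siRNA combination 1071 were higher and 1151 lower, of 16413. With median scaling the balance turned in both, to 808 higher and 773 lower in the microRNA and 1235 higher and 915 lower in the siRNA combination. Of the 1648 probes of the microRNA combination, 436 (26.5%) differed 2-fold the same way in at least 1 single microRNA, against 33.8 for independent lists, and 1208 differed 2-fold in none. Of the 2222 probes of the siRNA combination, 814 (36.6%) did so in at least 1 single siRNA, against 100.04, and 1405 in none. In simulated unchanged arrays that share the control, 11 of 27 probes (40.7%) of the microRNA and 4 of 33 (12.1%) of the siRNA combination did so. These simulated shares rest on few calls, so they cannot serve as the no-change share of the far longer measured lists. As counts, 436 and 814 probes were measured against 11 and 4 simulated. With 27 and 33 simulated calls in all, the simulated counts could not have come near the measured ones. They show only how few shared calls noise alone gives. The combination's differences correlated with the mean of its single agents at 0.62 for the microRNAs (slope 1.44) and at 0.79 for the siRNAs (slope 1.40). Simulated unchanged arrays that share the control gave 0.67 (slope 0.82) and 0.58 (slope 0.65), so the microRNA correlation was below its simulated value. A correlation depends on the spread of the differences, which in unchanged arrays is noise alone. The correlations therefore cannot decide whether the microRNA likeness exceeds that of unchanged arrays. The covariances were 0.110 and 0.252, against 0.025 simulated for both. Set against the sum of the single agents, the slopes were 0.36 and 0.70. The make-up and the amounts of RNA in the combinations are not given in the sources used here. With the miR-181b array in place of the control, the counts were 363 for the microRNA and 743 for the siRNA combination, and without background correction they were 817 and 1256.

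The 2 combinations resembled each other, and the difference between them followed siPIK3R3. Their differences from the control correlated at 0.86 across probes, against 0.53 simulated, with a covariance of 0.416 against 0.025 simulated, and 408 probes were at least 2-fold apart between them. The siRNA minus the microRNA combination correlated at 0.68 with siPIK3R3, set against the median of the 6 other arrays, and at 0.15 with miR-181b and 0.07 with siPIK3R1. The remaining 4 arrays gave -0.18 to -0.39. Of 545 probes at least 2-fold higher in siPIK3R3, 534 (98.0%) were higher in the siRNA than in the microRNA combination, against 47.4% of all probes compared, and 206 were so by 2-fold, against 10.5 for independent lists. Probes higher in miR-32 went the same way in 97.6% and those higher in miR-455 in 94.8%, many of them shared with siPIK3R3. By 2-fold, 40 of 83 higher probes of miR-32 did so, 50 of 96 of miR-455 and 100 of 308 of miR-181b. Independent lists gave 1.31, 1.56 and 5.09, so this excess among higher probes was not particular to siPIK3R3. Of 250 probes lower in siPIK3R3, 230 (92.0%) were lower in the siRNA than in the microRNA combination, against 52.5% of all probes compared. At 2-fold, 77 probes were higher in siPIK3R3 and the siRNA combination than in each of the 7 other arrays, with median folds over the control of at least 7.30 and 7.38, since only 37 of the 77 were detected in the control. They were chosen for being high in these 2 arrays. Of the 77, 35 were also at least 2-fold over the control in miR-181b, 33 in the microRNA combination and 28 in siPIK3R1. In miR-455 24 were, in miR-32 21 and in miR-181a 2, so a raised level was not always confined to the 2 arrays. For siPIK3R1 and the siRNA combination, 11 probes were set apart upward at 1.5-fold, against 163 for siPIK3R3 and the siRNA combination.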

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

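The reference arrays other than the median, the normalization without the combinations and the removal of shared probes were chosen after the results were seen. No paired analysis was possible because each group has 1 array. The mean of all probes of a gene, all alternatives for the gene lists, the seed sites and the target genes, and the other matchings of random lists were not run, because the probes have no gene names here. Of the alternative values for results that answer a comparison, 105 stayed within 1.5 times the main count or within 0.1 of a correlation, or kept their sign for the covariances, 26 counts were lower, 17 counts were higher, 6 correlations moved and 1 changed sign. Without background correction, the counts against the control were 59 for miR-32, 68 for miR-455, 43 for miR-181a, 242 for miR-181b, 817 for the microRNA combination, 319 for siPIK3R1, 458 for siPIK3R3 and 1256 for the siRNA combination, with 374 between miR-181a and miR-181b and 2 between miR-32 and miR-455. An offset of 50 gave 71, 83, 62, 328, 1073 and 434 for the first 6 of these, then 495 and 4 for the last 2 pairs. Both settings shrink differences of dim probes by construction, since they leave or add a constant below the log. Median scaling gave 15 probes between miR-32 and miR-455. The authors' processed values gave 205 for miR-32, 221 for miR-455, 227 for miR-181a and 61 between miR-32 and miR-455. Without a detection filter, that pair had 16 probes, and the correlations were 0.65 for miR-32 with miR-455, 0.28 for miR-181a with miR-181b and 0.46 for siPIK3R3 with the difference of the combinations. The median of the 8 other arrays as reference gave 42 for miR-455, 244 for miR-181a, 176 for miR-181b, 831 for the microRNA and 1385 for the siRNA combination. It gave correlations of 0.65 for miR-32 with miR-455, 0.50 for miR-181b with siPIK3R1, -0.54 for miR-181a with miR-181b and 0.73 for the combinations, and ILMN_1739441 was 0.40 higher in siPIK3R3. The lower threshold of 1.5-fold gave, by construction, 691, 851, 1170, 2708, 4947, 3788, 2729 and 5591 probes for miR-32, miR-455, miR-181a, miR-181b, the microRNA combination, siPIK3R1, siPIK3R3 and the siRNA combination, 3368 between miR-181a and miR-181b and 218 between miR-32 and miR-455. With miR-181b or siPIK3R1 in place of the control, the microRNA combination had 363 or 539 probes and the siRNA combination 743 or 987. The higher share was 9.46% for miR-32, 7.14% for miR-455 and 18.9% for miR-181a against the median of the 8 other arrays, where it was 75.5%, 76.2% and 34.9% against the control. It also moved by over 10 points without background correction for miR-32 (93.2%), miR-455 (88.2%), miR-181b (72.7%) and siPIK3R1 (71.5%), and between miR-32 and miR-455 it was 57.1% at first, 26.7% with median scaling and 11.5% in the processed values. At 1.5-fold the higher share was 54.0% for miR-32, 47.7% for miR-455, 46.2% for miR-181a and 50.2% for siPIK3R3. Normalization without the combination arrays gave 114 for miR-32 and 843 for siPIK3R3. Without the probes high in nearly all transfections, the correlation of siPIK3R3 with the difference of the combinations was 0.64. The cause of the other shifts was not tested. Signal over background limits the calls of dim probes, and the mean signal over the background level was lowest in siPIK3R1 (3.87) and miR-181b (4.12), then 4.20 in the siRNA and 4.48 in the microRNA combination.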

Other observations

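The tests of brightness on the first component, of the control array for the siRNA combination, of the shared seed, of an siPIK3R3 effect carried into the combination, of normalization and of control-like RNA were chosen after the results were seen. The remaining tests rest on analyses that were themselves chosen after the data were seen.

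The arrays of miR-181b, siPIK3R1 and both combinations lay apart from the other 5 on the first component. A candidate explanation is overall array brightness, because the brightest of the 4 had a mean raw signal of 361 and the dimmest of the other 5 had 392, an order that was seen before it was tested. A correlation of brightness with position over the 7 arrays other than the combinations was computed first and pointed the same way, but it is not given as the arrays fall into separate clusters. The control array alone is argued against for miR-181b with siPIK3R1. Their smallest correlation was 0.369 over references among miR-32, miR-455, miR-181a and siPIK3R3, which all lay on the far side of this component. It is not argued against for the siRNA combination, where the smallest correlation was 0.185. A response to the seed shared by miR-181a and miR-181b was not decided, since their covariance ran from -0.090 to 0.014 with the references chosen. On the first component miR-181a lay at 0.305 and miR-181b at -0.122, on opposite sides, with 1 array each. Brightness, RNA amount or quality and a real likeness of these transfections also stay open, since 1 array per group cannot separate them.

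The difference between the combinations followed the siPIK3R3 array, with a correlation of 0.68. This is consistent with an siPIK3R3 effect carried into the siRNA combination, a hypothesis, since the next array reached 0.15. The same 0.148 for miR-181b, the higher of the 2 dimmest single-agent arrays, argues against brightness alone as the cause. Yet siPIK3R1, miR-181b and siPIK3R3, with mean raw signals of 343, 361 and 392, were the dimmest of the single-agent and control arrays. They were also the only ones of these with a positive correlation, so a part played by brightness stays open. The composition of the combination and a shared handling of the siPIK3R3 and siRNA combination arrays stay untested.

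Some probes were set apart in 2 arrays only. At 1.5-fold, the pair of combinations had 208 probes lower and 107 higher than in every other array. The control and miR-181a had 84 lower, and siPIK3R3 and the siRNA combination had 36 lower. A normalization effect on the number of 84 is argued against, because the smallest number of such probes under 4 other normalizations was 67. Whether these were the same probes was not examined. An miR-181a array that holds RNA like that of the control stays open, because its correlations of 0.982 with the control, 0.989 with miR-455 and 0.986 with miR-32 lie close together and no repeat array gives their spread. Agents shared by a single-agent array and its combination cannot be told apart from other causes, because siPIK3R3 with the siRNA combination ranked 2 and siPIK3R1 with it ranked 6 of 35 pairs by lower probes, the pair of combinations left out, whereas by higher probes they ranked 1 and 2, with 163 and 11 probes against 10 for the next pair. A response to transfection that the control and miR-181a lacked may remain, and it was not tested.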
